A study of Homo sapiens with 44 samples.

How the data were processed

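Each library but the negative control, which received only spike-in RNA, was made from an aspirate of cytoplasm taken with a nanopipette from an iCell Neuron, per the labels' protocols. The RNA was converted to cDNA with SMART-Seq chemistry for very low input, with ERCC spike-in RNA added, amplified by PCR, tagmented with Nextera XT and sequenced as paired reads on an Illumina MiSeq, per the labels' protocols. A pair of read lengths is named there, with no statement of which library had which. The kit does not use molecular identifiers, so PCR copies of a molecule are counted separately and a few molecules can take most counts of a library. Whole-number counts per gene were deposited by the authors without normalization, 1 table per library. Alignment and counting used STAR and HTSeq on the hg38 build, per the submitters' processing notes, with versions not given in the sources used here. Strandedness, the treatment of reads that match several places and the gene annotation are not given there either, so reads shared with pseudogenes or overlapping genes cannot be separated.

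All 44 tables list the same 2013 genes, each with at least 1 count in some library, so the list itself may have been limited to counted genes. No ERCC row, no mitochondrially encoded gene and no row without a gene name was in the tables used here. The planned ratio of gene to ERCC counts and the fit without mitochondrial genes were therefore not run. No 2 libraries held identical counts. GENCODE release 29, on the same build, held 1894 of the symbols as given and 78 more through a synonym, and 41 were not matched. Coordinates are from that release, counted from 1.

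Groups follow the cell structure label of each library. The set number, cell number and order of aspiration come from the labels. Counts of aspirates of the same cell and compartment were summed, giving 13 cell body sums and 25 neurite sums, because the cell is the replicate. The labels do not tie cells to cultures or donors. The cell id, a label, pairs the compartments of 5 cells, and these were also tested with cell as a block. The main tests took all sums as independent, although these 5 cells entered with a sum of each compartment. In each of these 5 cells the cell body was aspirated after the neurite, so compartment and order of aspiration cannot be told apart in them. Set was a term in the main models or the stratum within which labels were shuffled, except in the alternatives without a set term, with cell as a block or within a single set.

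Genes entered tests with at least 10 counts over all sums and a count in 4 or more sums, which left 28 genes holding 37.0% of counts. Differences were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMMwsp factors from 0.0385 to 2.60, common dispersion 9.81) with Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are cell body minus neurite, and their standard errors are the ones implied by the p-value. DESeq2 1.42.0 and limma 3.58.1 (camera) served as alternatives. Detection, counts, genes per sum and the percent of counts in a gene list were compared by two-sided permutation tests with 100000 shuffles of the compartment within set, and pairs of the same cell by exact sign-flip tests. Thinning drew 30 counts from each sum, the 25th percentile of totals, leaving 28 sums. These steps ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Intervals are at 95%, a count of 0 is taken to allow 3 counts, and a pseudocount of 1 was used on log scales.

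Tables were simulated from the real means and library sizes for cell body against neurite (2013 genes, 20 simulations). In them edgeR recovered 72.4% of the 123 tested genes changed 16-fold and 90% of the 211 changed 64-fold. Most changed genes failed the gene filter and could not be called, so these percents do not describe all changed genes. edgeR also called 15.7% of unchanged tested genes in those tables and 12.7% of tested genes in tables without any change, above the nominal rate. The tables without change had 1578 tested genes over 20 simulations, more per table than the 28 of the real data. All simulated genes shared the common dispersion, so these rates may not carry over to the real data. The permutation test of a share of counts, tried on 1 simulated item with Poisson counts, recovered an 8-fold change in 100% of 200 simulations and called 2% of unchanged ones. Poisson counts spread less than the real counts, whose common dispersion was 9.81, so this recovery does not give the test's power on the real data. The permutation tests of detection, total counts and genes per sum were not simulated.

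Genes to be named, 27 gene lists and the alternatives were fixed before the data were examined. Named genes were those called by edgeR, the 5 with the smallest unadjusted p in each direction, the 5 detected in the largest share of sums per compartment (ties by mean CPM), up to 3 members of each list detected in most sums, and EOMES, HMGB3 and ACTB. Further counted members are named for the ion channel and skin lists, and the genes shared by aspirates of a cell are named, both chosen after their values were seen. Values of some single genes that the rule takes in are not reported here. Alternatives were other scalings, DESeq2, other gene filters, aspirates as units, no set term, cell as a block, each set alone, each of the 33 cells left out, higher detection thresholds and thinning. Fits to sums of 1000 or more counts were planned and could not be made with 3 such sums. The negative control entered no test between compartments.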

Results

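Small samples of cytoplasm were aspirated through a nanopipette from living human neurons, and the RNA of each aspirate was sequenced to ask which transcripts lie in the cell body and which in the neurites, the thin processes (axons and dendrites) that grow from it. The neurons were iCell Neurons, a commercial line of nerve cells differentiated from human induced pluripotent stem cells. The 44 libraries comprised 13 cell body aspirates, 30 neurite aspirates and 1 negative control that received only spike-in RNA. The aspirates came from 33 cells in a pair of numbered sets. Aspirates of the same cell and compartment were summed, which gave 13 cell body sums and 25 neurite sums, and 5 cells had both compartments sampled. No label names a culture or donor, so cells of a shared culture may stand in both groups. Every p-value below is over cells or aspirates, measures a spread that may be technical, and is too small for any claim across cultures or donors.

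The table lists 2013 genes, and the 43 aspirates held 11202 gene counts in all. An aspirate held between 11 and 2963 counts with a median of 56, and 30 aspirates held fewer than 100. Of the 2011 genes counted in an aspirate, 1697 (84.4%) were counted in 1 aspirate only and 1024 had a single count. The table totals cover listed genes only, so the number of reads sequenced per library is unknown. Reads were amplified by PCR without molecular identifiers, so intervals and limits for a count of 0 cover counting error only.

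Few genes had a count in more than a small share of the sums. TUBA1A, an alpha-tubulin of growing neurons, had a count in 5 of 13 cell body sums and 7 of 25 neurite sums. MAPT, which encodes the microtubule-binding protein tau, had one in 4 cell body sums and 8 neurite sums, and MAP1B, a microtubule-associated protein of growing axons, in 4 and 6. STMN2, a regulator of microtubules in growth cones, was counted in 4 sums of each compartment. In cell bodies the 5 genes of widest detection were TUBA1A, STMN2, MAPT and a pair of genes rarer in neurites, SET, a histone chaperone, and YWHAE, a 14-3-3 adaptor protein, each counted in 5 cell body sums and 2 neurite sums. In neurites the list held MAPT, TUBA1A, MAP1B, STMN2 and C17orf76-AS1, a long noncoding RNA with a count in 8 neurite sums and 2 cell body sums. Detection of 3 of these genes differed between the sets: MAPT was counted in 11 of 16 set 1 sums and 1 of 22 set 2 sums, whereas TUBA1A was counted in 0 of 16 and 12 of 22 and C17orf76-AS1 in 0 of 16 and 10 of 22. The adjusted p-values of Fisher's exact test over 28 genes were 0.00101, 0.00385 and 0.0179, and this comparison of sets was added after the data were seen. It took sums as independent, although the 5 set 2 cells sampled in both compartments entered with a sum of each. The 3126 counts of set 1 held no TUBA1A and no C17orf76-AS1 count, and 3 counts in 3126 is the limit that a count of 0 allows. The neurite of cell 23 holds 2268 of those counts, and without it the limit is 3 in 858.

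In the comparison of cell body with neurite sums, edgeR's quasi-likelihood test called 4 of 28 tested genes, 3 higher and 1 lower in cell bodies. RPL31, a protein of the large ribosomal subunit, had 10 counts in 4 cell body sums and 0 counts in 25 neurite sums. edgeR's test of the fitted fold of RPL31 gave an adjusted p = 0.00563. Against the limit of 3 counts that a count of 0 allows over all neurite sums, the pooled share of RPL31 was 5.01-fold higher in cell bodies. This limit takes the 10 cell body counts as exact, so it is no lower bound of the fold, and it was not tested. Single sums move this limit: it is 2.25-fold without set 2 cell 9, whose cell body held 6 of the 10 counts, 3.32-fold without the neurite of set 1 cell 23 and 13.3-fold without the cell body of set 2 cell 14. HSP90AA1, the stress-inducible cytosolic HSP90 chaperone, had 56 counts in 3 cell body sums and 4 counts in 2 neurite sums, a log2 fold change of 3.16 ± 0.89 (SE, adjusted p = 0.00568). YWHAE had 50 counts in 5 cell body sums and 21 in 2 neurite sums, a log2 fold change of 3.57 ± 1.25 (SE, adjusted p = 0.0293). MAPT was lower in cell bodies, with 12 counts in 4 cell body sums and 2247 in 8 neurite sums, a log2 fold change of -5.44 ± 1.61 (SE, adjusted p = 0.00692). As a percent of the counts of a sum, MAPT took 1.91% ± 3.82 in cell bodies (SD, n = 13) and 8.40% ± 21.6 in neurites (SD, n = 25), and 2212 of its reads lay in the neurite of set 1 cell 23. HSP90AA1 took 1.32% ± 3.20 and 0.0394% ± 0.174, YWHAE 3.35% ± 10.8 and 0.168% ± 0.582, and RPL31 0.698% ± 1.97 and 0% ± 0, on the same samples. The RPL31 mean rests largely on the cell body of set 2 cell 1, where RPL31 was 1 of 14 counts.

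These calls did not stand apart from shuffled labels. Of 100 splits of the sums drawn within the sets, the real one included, 63 gave 4 or more genes and the highest of the others gave 13. On simulated tables without any difference edgeR called 12.7% of tested genes. More genes per table passed the gene filter there than the 28 of the real data, so this rate may not carry over. DESeq2 gave a p-value to 21 of the 28 genes and called 0 of them, with 0 at an unadjusted p under 0.05. HSP90AA1 had a log2 fold change of 3.21 there, YWHAE 2.17 and RPL31 1.92, and MAPT, at -7.48, had no p-value. A permutation test of log2(CPM + 1), added after edgeR's result was seen, called 0 genes with 3 at an unadjusted p under 0.05 (RPL31, SET and YWHAE) and a lowest adjusted p of 0.211. With cell as a block, over the 5 cells sampled in both compartments, edgeR called 0 of 20 genes, 0 at an unadjusted p under 0.05; YWHAE was at 3.76, HSP90AA1 at 2.32 and RPL31 at 1.21 (each adjusted p = 0.994), and MAPT was not among the 20. Without a gene filter the folds of the 4 genes stayed about as large (3.22 for HSP90AA1, -5.38 for MAPT, 2.53 for RPL31 and 3.62 for YWHAE), with adjusted p-values of 0.0645 to 0.148 over 2011 genes. Without the 3 sums of 1000 or more counts, a restriction added after the data were seen, it called 2 genes, RPL31 and HSP90AA1, with YWHAE at a log2 fold change of 2.97 (adjusted p = 0.105) and MAPT at -1.59 (adjusted p = 0.486). MAPT lost its call without set 1 cell 23 (log2 fold change -2.01, adjusted p = 0.347) and without set 2 cell 17 (-3.02, adjusted p = 0.191), and YWHAE had a log2 fold change of 0.37 (adjusted p = 0.842) without set 2 cell 16, whose cell body held 33 of its 50 cell body counts. YWHAE was also no longer called without set 2 cell 3 (3.54, adjusted p = 0.0692), without set 2 cell 14 (3.07, adjusted p = 0.0697) or without set 2 cell 17 (3.47, adjusted p = 0.0567). HSP90AA1 was no longer called without set 1 cell 17 (2.10, adjusted p = 0.0980) or without set 2 cell 3 (1.93, adjusted p = 0.207), and RPL31 was no longer called without set 2 cell 9 (2.07 against 2.59 in the full data, adjusted p = 0.103), all by edgeR. The fitted folds of RPL31, which has 0 neurite counts, are no bound. In set 1 alone HSP90AA1 was the only one of the 4 still called, with MAPT at -6.92 (adjusted p = 0.0743), RPL31 at 1.26 (adjusted p = 0.135) and YWHAE at 0.63 (adjusted p = 0.616). All 21 set 1 counts of HSP90AA1 lay in the cell body of cell 17, so its call in set 1 rests on 1 library. In set 2 alone RPL31 and YWHAE were called, with MAPT at -4.73 (adjusted p = 0.0542) and HSP90AA1 at 2.76 (adjusted p = 0.148).

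No other named gene passed edgeR's adjusted threshold in the main fit, and many of them failed the gene filter and were not in that fit. SOX4 and SOX11, transcription factors of immature neurons, had log2 fold changes of 1.28 ± 0.61 (SE, adjusted p = 0.209) and 1.54 ± 1.01 (SE, adjusted p = 0.340). Of their cell body counts, 23 of 29 and 23 of 34 lay in set 2 cell 14, and as a mean percent of the counts of a sum SOX4 took 0.183% ± 0.357 in cell bodies (SD, n = 13) and 0.430% ± 1.5 in neurites (SD, n = 25). MARCKS, a membrane and actin-binding protein of growth cones, had a log2 fold change of 1.82 ± 1.03 (SE, adjusted p = 0.263). Of its 87 cell body counts 60 lay in set 2 cell 14, and it took 1.16% ± 2.18 in cell bodies (SD, n = 13) and 1.07% ± 3.57 in neurites (SD, n = 25). On the side of the neurite were C17orf76-AS1 at -2.40 ± 1.22 (adjusted p = 0.214), PTPRS, a receptor phosphatase of axons, at -1.47 ± 0.76, MORF4L1, a chromatin protein, at -1.75 ± 1.17, and RPL9 at -0.99 ± 0.73. Single neurites held much of this: 67 of 91 neurite counts of C17orf76-AS1 and 73 of 78 of MORF4L1 lay in set 2 cell 7, 8 of 12 of PTPRS in set 2 cell 4 and 16 of 19 of RPL9 in set 2 cell 8. The mean of log2(CPM + 1) had the opposite direction for MORF4L1 (set-adjusted difference 1.05) and RPL9 (0.34), as had the share of sums with a count (23.1% of cell bodies and 16% of neurites, and 15.4% and 12%). The folds moved with the scaling: the median log2 fold change over the 28 genes was 0.21 with the TMMwsp factors used here, 1.21 with TMM, 0.91 with DESeq2's size factors and 0.29 with library size alone. The corresponding calls were 3 higher and 1 lower, 2 higher and 1 lower, 5 higher and 1 lower, and 3 higher and 0 lower. YWHAE was not called with TMM (log2 fold change 1.35, adjusted p = 0.376) or with DESeq2's size factors (2.12, adjusted p = 0.174), and MAPT was not called with library size alone (-3.44, adjusted p = 0.149).

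The share of cells with a count differed for 0 of the 28 genes by permutation test with Benjamini-Hochberg adjustment, with 3 at an unadjusted p under 0.05. These were RPL31 (30.8% of cell bodies and 0% of neurites, p = 0.00882), SET (38.5% and 8%, p = 0.0306) and YWHAE (38.5% and 8%, p = 0.0364), and the lowest adjusted p was 0.247. The exact 95% binomial interval of RPL31 reached from 9.09% to 61.4% in cell bodies and up to 13.7% in neurites. MAPT was counted in 30.8% of cell bodies and 32% of neurites (p = 1).

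**Figure D1:**
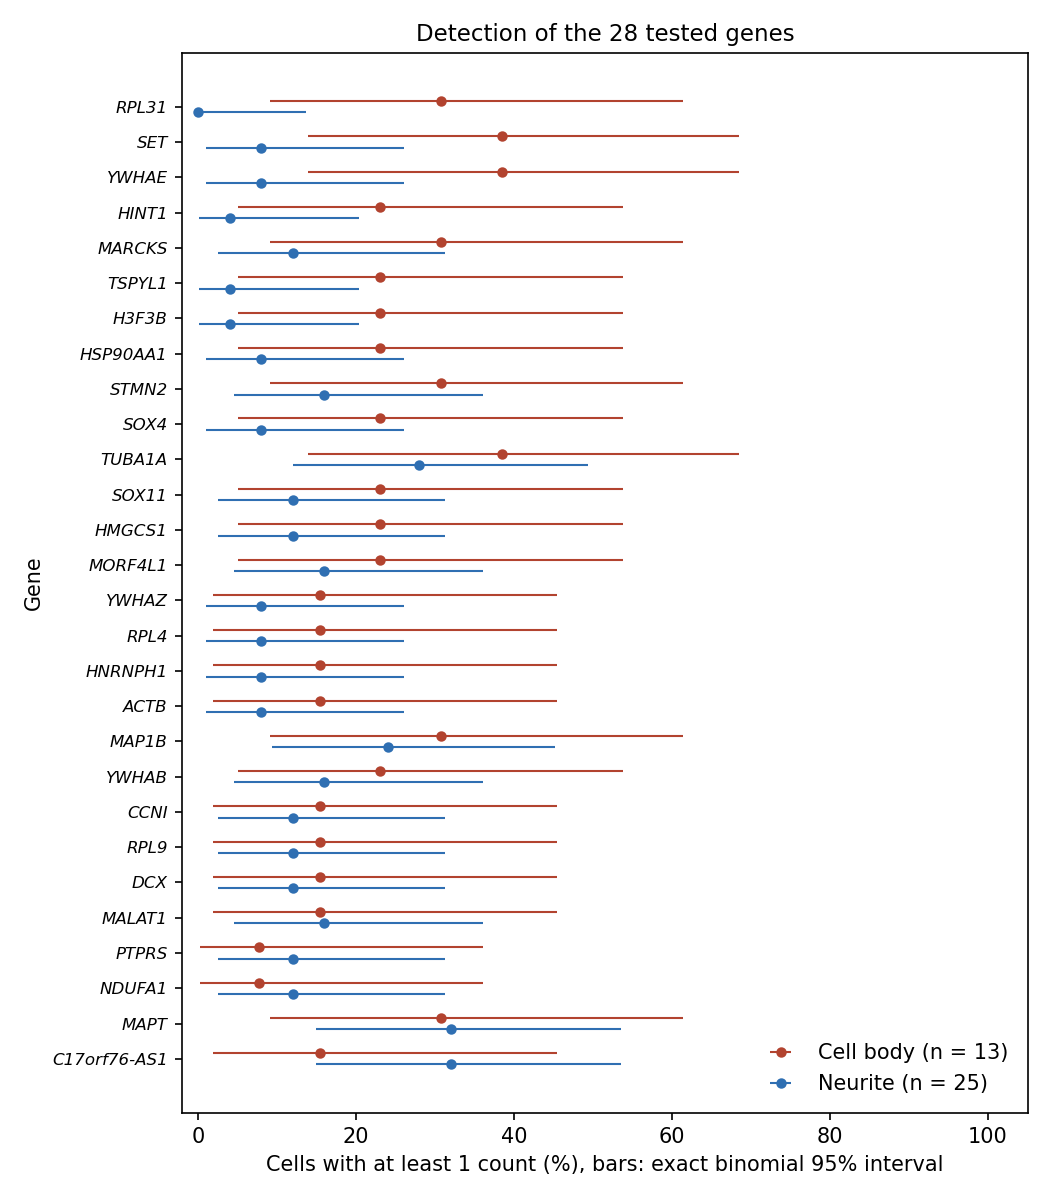
Percent of cells with at least 1 count of each of the 28 tested genes in cell bodies (red, n = 13) and neurites (blue, n = 25), with exact 95% binomial intervals as bars and genes ordered by the difference. RPL31 stands at 30.8% and 0% and C17orf76-AS1 at 15.4% and 32%, and the intervals of the compartments overlap for all 28 genes.

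Among gene groups fixed before the data were examined, 3 had 3 or more tested members, and none of them differed between compartments by permutation test of its percent of counts (0 of 3 at an unadjusted p under 0.05). Genes of microtubules and axon growth took 8.14% ± 6.57 of counts in cell bodies (SD, n = 13) and 15.6% ± 20.6 in neurites (SD, n = 25; p = 0.199), and were counted in 10 of 13 cell body sums and 20 of 25 neurite sums. Without MAPT, their most counted member, they took 6.23% and 7.16% (set-adjusted difference -0.76 percentage points against -7.84 with it), and without the 3 sums of 1000 or more counts the difference was -3.61. Of their 39 members 25 were counted in aspirates, 15 of them in both compartments, and 1 of 6 tested members, MAPT, passed edgeR's test, also adjusted over the list alone. Cytosolic ribosomal proteins took 3.29% ± 4.48 and 3.70% ± 11.3 (p = 0.978). The neurite mean rests on the sum of set 1 cell 13, where RPL5 took 13 of 23 counts: without it, a step added after the data were seen, the mean was 1.5% and the set-adjusted difference 2.01 percentage points (p = 0.0670), against -0.48 with it. The difference also had the other sign as a share of detected genes (3.49, p = 0.0769), in set 2 alone (3.46, p = 0.0507) and in the 5 paired cells (4.03, exact sign-flip p = 0.125). Of 79 members 36 were counted, 24 in cell bodies and 26 in neurites, and 1 of 3 tested members passed, also adjusted over the list alone: RPL31, beside RPL9 (2 counts in cell bodies, 19 in neurites) and RPL4 (4 and 6). RPL31 has 30 annotated pseudogene copies, and reads shared with them could be counted or lost, so its level is uncertain. Transcription and chromatin proteins took 2.66% ± 5.91 and 1.53% ± 2.93 (p = 0.458), with 0 of 3 tested members called, also adjusted over the list alone. Without their most counted member the direction turned, with 0.823% in cell bodies and 1.32% in neurites (set-adjusted difference -0.53 percentage points against 1.18 with it), as it did for their share of detected genes (-0.22). Set 2 cell 14 held 60 of their 98 cell body counts. The mean percent in cell bodies rests more on set 2 cell 1, where SOX11 took 3 of 14 counts (21.4%). Members of the list included SOX11 (34 counts in cell bodies, 5 in neurites), SOX4 (29 and 3) and H3F3B, a replacement histone (16 and 9). Camera, a test of a list against other genes, called 0 of the 3 lists with a preset and 0 with an estimated correlation, with lowest unadjusted p-values of 0.167 and 0.234.

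The other groups were too thinly counted for that rule, and 15 more lists were tested after the data were seen because 3 or more of their members had a count. None of the 18 lists then passed the adjusted threshold, and 2 were at an unadjusted p under 0.05. Ion channels and pumps had 16 counts in 4 of 13 cell body sums and 0 counts in 25 neurite sums (permutation p = 0.00832, adjusted p = 0.150). Members counted included the sodium channel subunits SCN2A, SCN3A and SCN3B, the sodium pump subunit ATP1B1 and the membrane scaffold ANK2, and ATP1B1 held 7 of the counts in 3 cell bodies. Set 2 cell 14 held 11 of the 16 counts. Heat shock proteins and chaperones took 1.79% ± 3.16 of counts in cell bodies (SD, n = 13) and 0.251% ± 0.713 in neurites (SD, n = 25; permutation p = 0.0169, adjusted p = 0.152), with HSP90AA1 ahead of TCP1, a subunit of the chaperonin (13 counts in cell bodies, 1 in neurites), and HSPA8 (4 and 3). HSP90AA1 alone held 56 of the 89 cell body counts, and as a share of detected genes the list took 1.01% and 0.327% (permutation p = 0.101, adjusted p = 0.604).

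Transcripts long described in dendrites or axons were counted in 6 cell body and 10 neurite sums, with 149 and 509 counts (permutation p = 0.807 for the share). MAP1B held 96 and 437 of them, 75 of the 96 in the cell body of set 2 cell 14 and 431 of the 437 in the neurite of set 2 cell 7. CALM2, named after its values were seen, had 12 and 40, each in 1 sum. Beta-actin, ACTB, had 4 and 9 counts in 2 sums of each compartment, and CTNNB1, beta-catenin, 8 and 1. Nuclear-retained long noncoding RNAs were counted in 3 cell body and 5 neurite sums (p = 0.934). MALAT1 had 143 counts in cell bodies, 142 of them in set 2 cell 14, and 15 in 4 neurites. KCNQ1OT1 had 18 and 1, and TUG1 had 1 and 0, and 17 of the 18 and the TUG1 count lay in the same cell body. Nuclear-encoded genes of oxidative phosphorylation had 31 and 80 counts over 33 counted members (p = 0.796), among them COX7A2 (0 and 8), NDUFA1 (2 and 9) and ATP5J (1 and 12). Translation factors had 48 and 28 counts (p = 0.694), among them EEF1A1 (10 and 5), EIF2S2 (0 and 5) and EIF4B (4 and 3). Actin cytoskeleton genes had 35 and 55 counts (p = 0.657), with ACTG1 at 5 and 3 and TMSB4X at 1 and 4. RNA transport and granule proteins had 35 and 21 (p = 0.565), with YBX1 at 0 and 6, NOVA1 at 0 and 4 and HNRNPK at 2 and 3. Ubiquitin and proteasome genes had 22 and 13 (p = 0.0561), with PSMB2 at 6 and 1, SKP1 at 3 and 4 and UCHL1 at 2 and 5. Motors and cargo adaptors had 23 and 15 (p = 0.535), with KIF21A at 3 and 0, KIF3A at 1 and 1 and DYNC1H1 at 2 and 2. Presynaptic and vesicle genes had 26 and 3 (p = 0.110), with SCG3 at 6 and 0 and SYT11 at 5 and 1, in 2 sums of each compartment. Postsynaptic genes had 11 and 17 (p = 0.720), with CAMK2N1 at 2 and 13, GRIN2A at 0 and 2 and NLGN3 at 0 and 1. Glycolysis genes had 9 and 1 (p = 0.120), with LDHB at 6 and 0, GAPDH at 3 and 0 and GPI at 0 and 1. These p-values are unadjusted, from permutation tests over 13 and 25 sums. Many of the cell body counts lay in set 2 cell 14: 25 of 26 for presynaptic and vesicle genes, with all 6 of SCG3 and 4 of 5 of SYT11, 11 of 11 for postsynaptic genes, 37 of 48 for translation factors, 27 of 35 for RNA transport, 18 of 23 for motors, 21 of 35 for actin genes, 13 of 22 for ubiquitin and proteasome genes, 6 of 9 for glycolysis and 13 of 31 for oxidative phosphorylation. Neurite counts were concentrated too: set 2 cell 8 held 31 of 55 for actin genes, 10 of 13 for ubiquitin and proteasome genes, 9 of 15 for motors, 10 of 28 for translation factors and 27 of 80 for oxidative phosphorylation, and set 2 cell 4 held 13 of 17 for postsynaptic genes. Of 20 immediate early genes, DUSP1 alone was counted, with 2 counts in a cell body. The 15 mitochondrially encoded genes were not in the table used here.

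Markers of cell types were rarely counted, and at this depth their absence was not informative. Glutamatergic markers had 5 counts in cell bodies and 1 in neurites (permutation p = 1 for the share of counts). TBR1 had 4 in cell bodies, and all 5 cell body counts lay in set 2 cell 14. GABAergic markers, GAD2 and SLC32A1, had 1 count each in a cell body. Astrocyte and radial glia markers had 7 and 1 counts, of which the glutamate transporter SLC1A2 held 6 and FABP7 1 in each compartment. The cell body of set 2 cell 14 held 6 of the 7. Mesenchymal cells were represented by 1 count of COL3A1. Skin cell genes, fixed as signs of handling, had 3 and 2 counts (KRT10, FLG, KRT5 and DSP; permutation p = 0.978). Markers of progenitor and dividing cells, oligodendrocytes, pluripotent cells and blood cells had 0 counts in 11202, a limit of 3 counts.

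EOMES and HMGB3 were counted in neurites alone, in too few sums to enter the main test. EOMES, a T-box transcription factor (GRCh38 chromosome 3, 27715949 to 27722711, protein-coding), had 1 count in 1 neurite aspirate, of set 2 cell 5. HMGB3, a chromatin protein (chromosome X, 150980509 to 150990775), had 3 and 7 counts in 2 neurite aspirates, of set 1 cell 8 and set 2 cell 12, and 0 counts in cell bodies. HMGB3 has 29 annotated pseudogene copies, so its level is uncertain. ACTB lies on chromosome 7 from 5527147 to 5563784. The called genes lie on chromosome 2 (RPL31, 101001715 to 101024032), chromosome 14 (HSP90AA1, 102080738 to 102139699) and chromosome 17 (YWHAE, 1344272 to 1400378, and MAPT, 45894382 to 46028334). All are protein-coding in GENCODE release 29, and each count covers the whole gene.

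Cell bodies did not yield detectably more gene counts than neurites. On the scale of log2(counts + 1), cell body sums had 6.59 ± 2.16 (SD, n = 13) and neurite sums 6.31 ± 2.07 (SD, n = 25; set-adjusted difference 0.36, two-sided permutation p = 0.606). A cell body held 110 ± 236 genes (SD, n = 13) and a neurite sum 42.4 ± 40.2 (SD, n = 25; set-adjusted difference 72.5, permutation p = 0.0922). The deepest cell body library, of set 2 cell 14, held 2963 counts and 869 genes. Without the 3 sums of 1000 or more counts, a restriction added after the data were seen, the difference was 11.9 genes (permutation p = 0.485). With every sum thinned to 30 counts, which 11 cell body and 17 neurite sums allowed, 20.4 ± 7.04 genes were counted in cell bodies (SD, n = 11) and 16.9 ± 6.94 in neurites (SD, n = 17; difference 4.17, permutation p = 0.143). In the 5 cells with both compartments the mean differences had the opposite sign. Cell body minus neurite was -0.35 ± 1.64 on the log2 scale (SD, n = 5; exact sign-flip p = 0.875) and -16 ± 27.7 genes (SD, n = 5; exact sign-flip p = 0.3125), with more counts in the cell body of 3 of 5 cells and more genes in that of 1. In cells 3, 4 and 16 the neurite sum pools 2 aspirates against 1 of the cell body. The cell body was aspirated after the neurite in all 5 cells, so these differences cannot separate compartment from order of aspiration. The smallest p that 5 pairs allow is 0.0625.

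**Figure D2:**
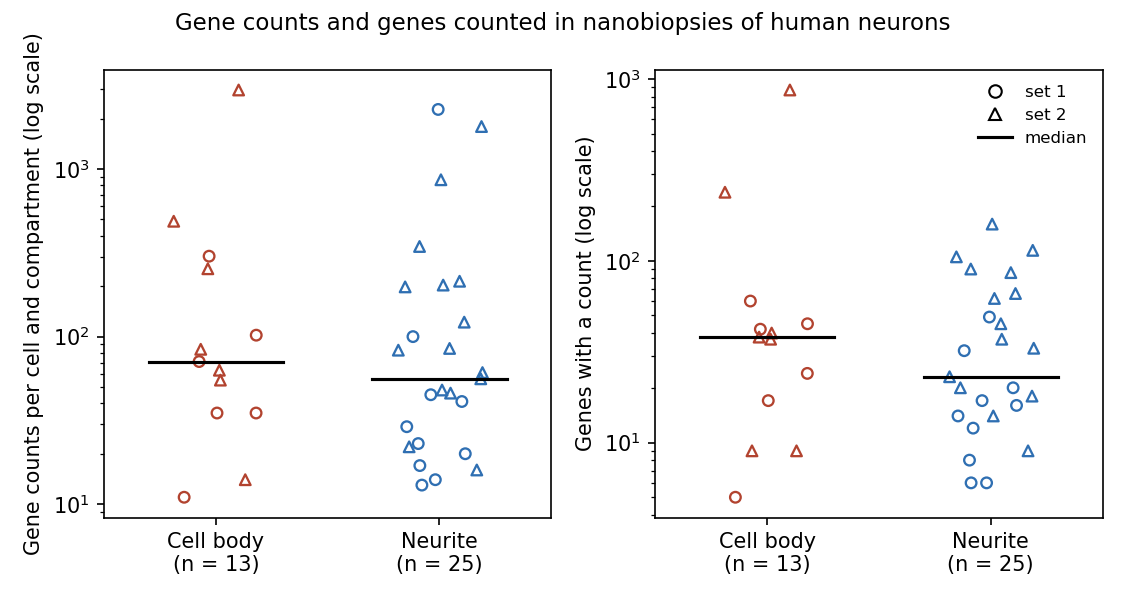
Gene counts (left) and genes with a count (right) per cell and compartment on log scales, for 13 cell body and 25 neurite sums, with circles for set 1, triangles for set 2 and lines at the medians. Median counts are 71 in cell bodies and 56 in neurites, and the highest cell body stands at 2963 counts and 869 genes.

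Cell body and neurite of the same cell shared few counted genes, at 14 to 254 counts per sum. Repeated neurite aspirates of a cell shared few genes too, so this shows no difference between compartments. Set 2 cell 3 had 8 genes counted in both compartments (ACTB, C17orf76-AS1, COX6C, NDN, SET, STMN2, TUBA1A and YWHAZ), cell 1 had SOX11, and cells 4, 15 and 16 had 0. Over 25 usable set 2 aspirates, the Spearman correlation across filtered genes averaged 0.113 for 10 same-cell pairs and 0.041 for 290 pairs of different cells (one-sided permutation p = 0.101). Of the 10 same-cell pairs, 5 joined neurite aspirates with each other. Genes are not independent replicates in such a correlation. Without a gene filter, over 27 aspirates with 13 same-cell and 338 other pairs, the averages were 0.0202 and 0.000563 (one-sided permutation p = 0.0268).

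A later neurite aspirate was compared with an earlier one in 5 cells. Repeated aspirates shared 0 to 2 genes: STMN2 in cell 3, C17orf76-AS1 and PDS5B in cell 4, EIF4B and TUBA1A in cell 10, MAP1B in cell 12 and none in cell 16, all of set 2. The later aspirate held fewer genes in 4 of 5 cells, by a mean difference of -18.8 ± 25.9 genes (SD, n = 5; two-sided exact sign-flip p = 0.1875) and -8.75 without cell 10, and its log2(counts + 1) differed by -0.13 ± 0.95 (SD, n = 5; exact sign-flip p = 0.9375). Without cell 10 the mean difference in log2 counts was 0.27. A p below 0.0625 was out of reach with 5 pairs.

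The negative control held 2 gene counts, 1 of L1CAM and 1 of TIMM23, against 11 to 2963 in the aspirates. Neither gene had a count in any aspirate. With 1 control library there is no test.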

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

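The comparison of detection between the sets, the split of the cell body pattern into its genes, the comparison of its 3 genes with the highest of each shuffle, the control genes for reads crossing between libraries and the relation of MAPT reads to depth were chosen after the results were seen. Among 13 groups of 5 to 10 values, 6 held a value far from the others by Dixon's gap ratio. The 15 neurite sums of set 2 were not tested in this way. Its chance rate of about 1 in 20 groups holds for normal values. Counts, genes and percents per sum were compared untransformed and are skewed, so the chance rate here is unknown and skew alone may give such values. The cell body of set 2 cell 14 had 2963 counts and 869 genes, next to 488 and 238 in the nearest cell body of its set. The neurite of set 1 cell 23 had 2268 counts, next to 100. The cell body of set 1 cell 17 had 302 counts, next to 102. The most counted gene held 63.6% of the counts in the cell body of set 1 cell 7 (WDR47, 7 counts) and 51.2% in that of set 2 cell 16 (TAX1BP1, 43 counts). Of 5 differences between compartments compared across the sets by permutation, 1 had an unadjusted p under 0.05. The share of transcription and chromatin proteins, cell body minus neurite, was -1.88 percentage points in set 1 and 3.58 in set 2 (p = 0.0333, not adjusted for the 5 comparisons). The set 2 cell body mean, 4.65% ± 7.71 (SD, n = 7), rests largely on cell 1, where SOX11 took 3 of 14 counts (21.4%).

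MAPT was lower in cell bodies than in neurites by edgeR, and was counted in 11 of 16 set 1 sums but 1 of 22 set 2 sums. The fold rests on few libraries: without the neurite of set 1 cell 23, with 2212 of 2247 neurite reads, its adjusted p was 0.347, over a range of 0.00355 to 0.486 across the other planned and added settings that gave a value. The other 15 set 1 sums held 1 to 4 MAPT reads in 10 cases, whether the remaining counts were 11 or 300, and Spearman's rho between MAPT reads and the remaining counts was -0.145 (permutation p = 0.592, bootstrap 95% interval -0.614 to 0.400). Reads crossing over from the library of 2212 may have added these few counts: 6 other genes with 100 or more counts in a library were also counted in a larger share of the other sums of that set than of the other set (10.4 percentage points, one-sided permutation p = 0.0174). Set 2, which holds all 6, is also deeper, and 79 genes with at least 10 and fewer than 100 counts in a library showed a difference of 4.19 points (p = 0.0827 for the 6 against the 79), so crossing reads and MAPT captured from each cell cannot be told apart here.

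RPL31, HSP90AA1 and YWHAE were higher in cell bodies by edgeR. The deepest cell body library held 1 of the 10 RPL31 and 10 of the 56 HSP90AA1 counts in cell bodies. Without it their edgeR adjusted p was at most 0.00500. It held so few of their counts that this fit says only that the calls do not rest on it. Other single cells did end them: set 2 cell 9 for RPL31, and set 1 cell 17 or set 2 cell 3 for HSP90AA1. YWHAE lost its call without the deepest library with a log2 fold change of 3.07 ± 1.19 against 3.57 ± 1.25 with it (SE, adjusted p = 0.0697), so the call ended by a small change and that library's part in it cannot be told apart from chance. Without the cell body with 33 YWHAE reads the log2 fold change was 0.37 ± 0.86 (SE, adjusted p = 0.842), so those reads may account for it. Greater depth of cell body libraries cannot be told apart from a difference in these genes: at 30 counts per sum the mean chance of detecting the 3 genes was 13.8% in cell bodies and 2.51% in neurites (permutation p = 0.0257), which met the bound set beforehand, but that bound was wrong because genes picked for being higher in cell bodies meet it by their choice. Against the 3 highest of the 28 genes in each shuffle the p was 0.777, and the median difference in the shuffles was 14.7 percentage points against the real 11.7.

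The number of called genes, 4, was reached or passed in 63 of 100 splits of the sums within the sets, and the highest of the other splits gave 13 genes. Chance is therefore not excluded as the origin of the count, and no explanation by compartment is needed for it. Compartment, the difference the design names, remains open as an explanation and is not shown by these calls.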

How the results depend on the processing

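Removal of sums of 1000 or more counts, the permutation test of log2(CPM + 1) per gene and the wider choice of lists were added after the data were seen, as were lists without the neurite of highest ribosomal share and the pairs of repeated aspirates left out in turn. The count of genes differing between compartments was 4, and between 3 and 6 under TMM, DESeq2's size factors, library size alone, no set term, each aspirate as its own library or each set alone. The last shared 1 (set 1) and 2 (set 2) of the 4, TMM and DESeq2's size factors lost YWHAE, and library size alone lost MAPT. It was 0 with DESeq2 (21 of 28 genes with a p, 0 unadjusted), 0 with the replicate block of 5 cells (20 genes tested, 0 unadjusted) and 0 with the permutation test (3 unadjusted). It was 1 of 2011 without a gene filter (TAX1BP1, with 477 unadjusted; the folds of the 4 stayed about as large, adjusted p 0.0645 to 0.148), 1 of 4 with the stricter filter on the share of sums with a count (MAPT) and 2 without sums of 1000 or more counts. Leaving out each of 33 cells gave 2 to 6 genes, with all 4 of the full data in 26 fits. The stricter filter and the block tested fewer genes; otherwise the cause was not tested. Removing genes counted in the negative control removed no tested gene and says nothing.

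Detection of genes and shares of gene lists gave 0 calls in the full data and under each alternative that could be run. Gene counts per cell differed by 0.36 on the log2 scale, by 0.61 with each aspirate as its own library and by -0.35 in the paired cells of the replicate block. Genes per cell differed by 72.5, by 83.0 with each aspirate as its own library (permutation p = 0.0373) and by -16 in the replicate block. In set 1 alone they differed by 14.2 and in set 2 alone by 118. The similarity of aspirates of the same cell was 0.0721 above that of other pairs and, without a gene filter, 0.0196 above it (p = 0.0268). In the paired cells the number of cells fell to 5 and the cell body was aspirated last in each. For the other changes the cause was not tested. Leaving out each pair of repeated aspirates gave differences in log2 counts of -0.31 to 0.27, and without set 2 cell 10 the sign turned. Not run were the ERCC ratio and the fits without mitochondrial genes, for which no rows were used here, and fits, detection and lists over sums of 1000 or more counts, of which there were 3. Depth limits all of this: 24 of 38 sums held under 100 counts.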

Other observations

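Gene groups chosen after the data were seen add to this picture. Of 7 genes for 14-3-3 proteins, abundant adaptors of neurons, 6 were counted, in 8 of 13 cell body sums (74 counts) and 5 of 25 neurite sums (60 counts). YWHAE led in cell bodies (50 counts, 33 of them in 1 sum), YWHAB had 8 counts in 3 cell body sums and 11 in 4 neurite sums, YWHAG had 7 and 0 and YWHAQ 3 and 15. Of 18 genes of sterol synthesis and its control, 5 were counted. HMGCS1, which makes a precursor of cholesterol, had 46 counts in 3 cell body sums, 34 of them in set 2 cell 14, and 18 in 3 neurite sums, with a mean of 0.316% of counts in cell bodies and 0.435% in neurites, and INSIG1 2 counts in 2 neurite sums. The group totals were not tested; of the single genes, YWHAE, YWHAB and HMGCS1 were among the 28 tested by edgeR (adjusted p = 0.0293, 0.885 and 0.605).

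Genes counted in 3 or more sums of 1 compartment and 0 of the other were few. In neurites they were COX7A2, a subunit of cytochrome c oxidase (8 counts in 3 sums), TMA7 (5 in 3) and MARCKSL1 (3 in 3). In cell bodies they were RPL31 (10 in 4), SKA2 (16 in 3), the splicing regulator TRA2A (16 in 3), the nuclear RNA-binding protein NONO (10 in 3) and ATP1B1 (7 in 3). They were picked for this difference and not tested as a group.

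If the compartments held different transcripts, fewer genes should be counted in both than chance gives. Of 1291 genes counted in cell bodies and 928 in neurites, 208 were counted in both, against a median of 170 and a 95% range of 96 to 222 in 10000 shuffles of the labels within set (permutation p = 0.813 for fewer). No separation of transcripts showed in this measure. The test does not decide, since 84.4% of genes were counted in 1 aspirate only and such genes lie in 1 compartment by necessity.

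A library ruled by its most counted gene may have come from very few captured molecules, and this was compared between compartments after the library totals had been seen. The most counted gene held 17.97% ± 18.4 of counts in cell bodies (SD, n = 13) and 26.5% ± 22.5 in neurites (SD, n = 25; permutation p = 0.208). The difference is within the spread of these sums, and an effect of compartment stays open. In the neurite of set 2 cell 7, UBE2W held 529 of 1793 counts, and in that of set 2 cell 5, RYBP held 153 of 345.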
